A study of Arabidopsis thaliana with 8 samples.

How the data were processed

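RNA sequencing of 8 libraries was analysed, 2 for each of 4 groups: Col-0 wild type and irx3-2, each on MS medium and on MS medium with lincomycin. Groups and replicate numbers were taken from the labels. Libraries were made from total RNA with an Illumina kit, and the labels do not say whether the kit kept the strand.

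Per the submitters' processing notes, the tools were Trimmomatic, FastQC, TopHat2 2.1.1, featureCounts and DESeq2, with TAIR10 as the genome; the strand setting, the handling of reads that fit several places and the annotation version are not stated. The authors deposited 4 tables, 1 per pairwise comparison, each with 36917 loci. Per the file headers and the values, 8 columns of each table hold normalized counts (a signal scaled by 1 size factor per library), and the deposited base mean is their mean. Per the file headers, the authors also deposited log2 fold changes with standard errors (log2 scale) and the p-value and adjusted p-value of DESeq2. The 8 columns were identical in the 4 tables. In every column all values were whole multiples of 1 number to within 0.01, so whole reads were recovered by division, and the recovered totals were 15032240 to 19488440 reads per library. The size factors were those of the median-of-ratios method. Of the 36917 loci, 4890 were at 0 in all libraries and 36632 were found in the RefSeq gene table of TAIR10.1, from which positions and overlaps were taken; symbols came from the deposited tables and that gene table.

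The main test was limma 3.58.1 with a mean-variance trend (R 4.3.3) on log2 of the normalized count plus 1, for the 20251 genes with at least 10 normalized counts in at least 2 libraries. All 8 libraries were fitted at once with 4 group means, which leaves 4 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The 5 comparisons were lincomycin against MS in wild type and in irx3-2, irx3-2 against wild type on MS and on lincomycin, and the interaction, which is the lincomycin effect in irx3-2 minus that in wild type. Before the data were examined, the comparisons, the gene lists, the rule for named genes and most alternatives were fixed, with edgeR's quasi-likelihood test on counts as the main test. Because the deposited unit was normalized counts, limma took its place, which is a departure from the plan. The planned test, edgeR 4.0.16 with TMM, was run on the recovered reads as an alternative.

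A total of 24 gene lists with 381 genes were fixed before any value was seen. For plastids they were light-harvesting antenna, nuclear photosystem and electron transport, Calvin-Benson cycle, tetrapyrrole synthesis, retrograde and greening regulators, plastid-encoded photosynthesis genes, plastid-encoded genes read by the nuclear-encoded polymerase, plastid ribosomal proteins and plastid transcription machinery. For walls, metabolism and stress they were secondary wall and xylem, primary wall cellulose, phenylpropanoid, flavonoid and anthocyanin, glucosinolate, jasmonate, salicylate and pathogen response, abscisic acid and dehydration, mitochondrial dysfunction stimulon, and heat shock and plastid folding. The others were seed storage and maturation, root markers, phloem markers, circadian clock and reference genes. Each list was tested against all other genes with camera in limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg over the lists of a comparison. With the correlation estimated from the data, no list was called in any of the 5 comparisons, so each camera call depends on the preset setting. Fry, which tests each list on its own and uses no preset correlation, is given in the closing part. The estimated setting also gave a higher p where genes were not correlated. DNA damage genes, a group added later, had an estimated correlation of −0.0301. Their unadjusted camera p for lincomycin in wild type was 8.55e-10 with the preset value and 0.00285 with the estimate. In simulated data a shifted list of 20 genes, each simulated on its own, had an unadjusted camera p of 2.09e-62 with the preset value. With the estimate it was 5.30e-05. A call lost with the estimate therefore does not by itself show that the members move together. At an unadjusted p below 0.05 the estimated correlation gave 7 lists for lincomycin in wild type and 8 in irx3-2. It gave 1 between the genotypes on MS, 5 on lincomycin and 4 for the interaction. Members past the threshold were counted over all genes tested and adjusted over the list alone. In 14 of the 120 list tests the median, the mean and the test differed in sign, and 0 of these 14 passed. Members at 0 reads in every library were LHCB1.5, PRPS17, MYB58, MYC2, PDF1.2B, PDF1.3 and HSP17.4. Of 541 protein-coding genes covered to at least 90% by other genes 65.4% were at 0 in every library, against 5.47% of 19367 that overlap no gene, so a level of 0 or a low level of an overlapped gene is not read as absence.

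The named genes were CESA7 and LHCB1.2 in every comparison, and the 6 largest rises and 6 largest falls past the threshold with groups that do not overlap and a mean of at least 5 CPM, which is reads scaled to the library total. For the interaction the overlap condition was left out. Up to 4 members per list were added, those past the threshold with the largest change first. The slope of the irx3-2 response on the wild-type response was the first principal axis through the origin over genes past the threshold for the mean lincomycin effect. Its jackknife spread was computed over the 8 libraries as if they were 1 group. It therefore does not follow the 4 groups of 2 and is a rough measure. A fold against a group with 0 reads was computed against a floor of 3 reads over the 2 libraries of that group, and with 1 to 3 reads the ratio is given with its exact 95% counting interval. Bounds and intervals cover counting error only.

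The alternatives were edgeR with median-of-ratios size factors, DESeq2 1.42.0, no filter, a filter of at least 10 CPM in 2 libraries, a replicate block, organelle genes removed, only the 4 libraries compared, the authors' adjusted p and each library left out in turn. The planned main test, edgeR with TMM, was run on the recovered reads as a further alternative. Pseudocounts of 0.5 and 5 and TMM scaling were chosen after the data were seen. For lists an estimated correlation and fry were run. With a library left out, the lone library of its group is assumed to vary like the other groups. Regroupings of the samples were not counted, since each group held 2 libraries. The tests were checked on simulated data built from these libraries with 200 changed genes. In them limma recovered 36% to 75% of 2-fold and 83% to 98% of 4-fold changes over the 5 comparisons, and 4% to 10.2% of its calls were false. The simulation gave each gene the same spread beyond counting error in all 4 groups. In the real data lincomycin changed 5921 genes in wild type and 6835 in irx3-2, so these rates need not carry over. For lincomycin in wild type, 1.5% of 200 unchanged lists had an unadjusted camera p under 0.05. Those lists were drawn at random and each gene was simulated on its own. The check therefore does not cover lists whose genes move together.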

Results

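Total RNA from whole Arabidopsis thaliana seedlings, 5 days old, was sequenced after growth under continuous light of 100 µmol photons m-2 s-1 on Murashige and Skoog (MS) medium or on MS medium holding lincomycin at 50 µg/ml. Lincomycin is an antibiotic that blocks translation on plastid ribosomes. The seedlings were wild type (Col-0) or irx3-2, a mutant allele of IRX3, the gene of CESA7, a cellulose synthase subunit of the secondary cell wall. Each of the 4 groups held 2 libraries, and the libraries held 15032240 to 19488440 counted reads. The series title poses the question whether a secondary wall defect lessens the effect of lincomycin on early chloroplast development. The response to lincomycin was measured in each genotype, then the genotypes were compared on each medium, and last the responses were tested against each other. The labels do not say whether the 2 libraries of a group came from separately grown plants, so the p-values measure the spread between these samples.

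Plastid-encoded genes took 54.6% ± 0.643 of the counted reads (SD, n = 2) in wild type on MS and 56.6% ± 2.02 in irx3-2 on MS. On lincomycin the share was 20.0001% ± 0.608 in wild type and 19.7% ± 1.38 in irx3-2. Fewer reads were therefore left for nuclear genes on MS, where counting error was larger. The 18S ribosomal RNA gene (AT3G41768) varied within groups as well as between them, with 249.7 and 701924 normalized counts in the 2 wild-type MS libraries and 33855 and 503 in the 2 irx3-2 MS libraries. Across genes, which are not independent replicates, the Pearson correlation of log2 values between the 2 libraries of a group was 0.950 to 0.984, and between libraries on different media it was 0.847 to 0.891.

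CESA7 (AT5G17420, chromosome 5, 5736630 to 5741500, minus strand, TAIR10.1) was the gene mutated in irx3-2, and its transcript was present in both genotypes. Its level was 271 ± 9.08 normalized counts (SD, n = 2) in wild type on MS, 216 ± 8.64 in wild type on lincomycin, 712 ± 0.294 in irx3-2 on MS and 348 ± 75.9 in irx3-2 on lincomycin. CESA7 was thus 2.62-fold higher in the mutant on MS (log2 1.39 ± 0.16 SE, adjusted p = 0.00760) and 1.59-fold higher on lincomycin (0.67 ± 0.16, adjusted p = 0.0347). The second of these calls was lost without any 1 of the 4 lincomycin libraries, with an adjusted p of up to 0.284. The labels do not give the irx3-2 lesion, and the counts are summed per gene, so the transcript level does not check the genotype of a library. LHCB1.2 (AT1G29910, chromosome 1, 10472280 to 10473502, minus strand), a chlorophyll-binding antenna protein of photosystem II, stood at 49472 ± 33.7, 807 ± 16.3, 67260 ± 6832 and 1017 ± 94.1 normalized counts in the same order of groups. LHCB1.2 shares nearly all of its sequence with LHCB1.1 and LHCB1.3, and how reads that fit several places were counted is not stated.

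Lincomycin lowered the transcripts of photosynthesis in wild type. All 20 tested genes of the light-harvesting antenna fell, as did all 32 nuclear genes of the photosystems and electron transport chain, all 18 genes of the Calvin-Benson cycle and all 23 plastid-encoded photosynthesis genes. Their median log2 changes were −3.97, −3.57, −3.14 and −3.41, and changes given without a unit here are on the log2 scale, with the SE of the fit. LHCB1.2 fell 61.2-fold (log2 −5.94 ± 0.11 SE, adjusted p = 1.36e-10), and LHCB1.4 (AT2G34430, −7.67 ± 0.13) and the plastocyanin gene PETE1 (−5.62 ± 0.18) fell too. RBCS2B (AT5G38420), a small subunit of Rubisco with close copies in the genome, changed by −7.40 ± 0.18. The plastid-encoded RBCL, the large subunit of Rubisco, changed by −6.17 ± 0.23, and PSBA, the D1 protein of photosystem II, by −4.77 ± 0.29. Adjusted over the list alone, all members of these 4 lists again passed. The lists passed camera at adjusted p = 3.80e-30, 3.12e-43, 9.95e-25 and 1.41e-26, in the order above, and each gave adjusted p = 0.116 with an estimated correlation.

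The rest of the chloroplast programme split by function in wild type. Of 27 genes of tetrapyrrole (chlorophyll and heme) synthesis, 24 fell and 1 rose, the ferrochelatase gene FC1 (0.49), with the same counts adjusted over the list alone. The protochlorophyllide reductase genes PORB and PORC fell (−3.87 ± 0.09 and −2.89), and the list median was −1.67 (camera adjusted p = 1.69e-20, and adjusted p = 0.116 with an estimated correlation). All 23 nuclear genes of plastid ribosomal proteins fell, over all genes and adjusted over the list alone, with a median of −1.52 (adjusted p = 4.31e-22, and adjusted p = 0.152 with an estimated correlation). In contrast, of 8 plastid genes that are read by the nuclear-encoded plastid RNA polymerase, 5 rose and 1, ACCD (−0.48), fell, over all genes and adjusted over the list alone. The 8 include YCF2.1 and YCF2.2, copies of the same gene, which are not independent members. RPOC2, RPOB and RPOC1, subunits of the plastid-encoded polymerase, rose by 1.88 ± 0.26, 1.85 and 1.54, and the list median was 0.91 (adjusted p = 0.0179, and adjusted p = 0.327 with an estimated correlation). Of 13 genes of the plastid transcription machinery, the sigma factor genes SIG1, SIG2, SIG4 and SIG6 fell (−1.70, −1.38, −1.97 and −0.75), while the polymerase genes RPOTP and RPOTMP rose, RPOTP by 0.86. SIG4 is covered to 11.1% by another gene. Adjusted over the list alone 3 rose and 4 fell, and the list was not called (median −0.33, adjusted p = 0.332). Among 9 retrograde and greening regulators GLK1, CGA1, GLK2 and HO1 fell (−1.55, −1.44, −0.83 and −0.81) and none rose. Adjusted over the list alone 2 rose and 5 fell, and the list was not called (median −0.26, adjusted p = 0.143).

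**Figure D1:**
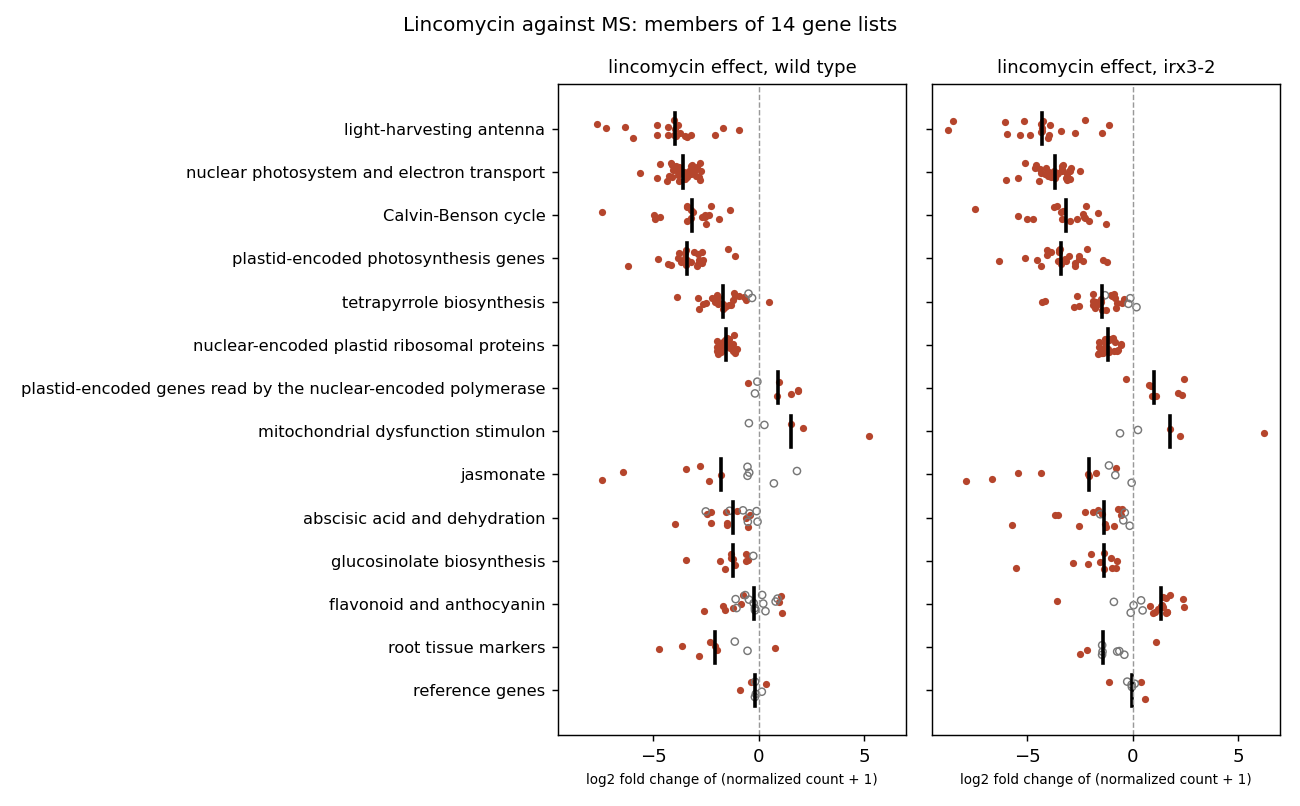
Log2 change on lincomycin against MS (horizontal axis) of each tested member of 14 gene lists, in wild type (left) and irx3-2 (right). Filled red points passed adjusted p = 0.05, open grey points did not, and the black bar is the list median; antenna medians lay at −3.97 and −4.29.

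Hormone and stress genes also moved on lincomycin in wild type. Of 11 jasmonate genes 6 fell and none rose, or 7 adjusted over the list alone, led by the biosynthesis genes AOC2 (AT3G25770, −7.42 ± 0.30), LOX2 (−6.42 ± 0.14) and AOS (−3.46). The jasmonate list had a median of −1.79 (camera adjusted p = 1.32e-04, and adjusted p = 0.234 with an estimated correlation). AOC2 lies beside its close copy AOC1. Of 18 abscisic acid and dehydration genes 11 fell, or 12 adjusted over the list alone, among them the cold-regulated genes COR15A (−3.94 ± 0.53) and KIN1 (−2.45). The list median was −1.19 (camera adjusted p = 3.71e-05, and adjusted p = 0.176 with an estimated correlation). Of 11 glucosinolate synthesis genes 10 fell, over all genes and adjusted over the list alone, with CYP79F1 at −3.43 and a median of −1.21 (adjusted p = 1.15e-05, and adjusted p = 0.116 with an estimated correlation). Of 17 general phenylpropanoid genes 11 fell and 1 rose, or 13 and 1 adjusted over the list alone, among them PAL4 (−1.61) and 4CL1 (−1.23). The list median was −0.67 (camera adjusted p = 3.71e-05, and adjusted p = 0.234 with an estimated correlation). Of 5 genes of the mitochondrial dysfunction stimulon 3 rose, over all genes and adjusted over the list alone. UPOX rose by 5.24 ± 0.26, ANAC013 by 2.09 and the alternative oxidase AOX1A by 1.53 (list median 1.53, adjusted p = 0.00760, and adjusted p = 0.140 with an estimated correlation). Of 13 heat shock and plastid folding genes 7 fell, among them VIPP1 (−1.25) and the plastid chaperone genes CPHSC70-2 (−1.13) and CPN60B1 (−1.08). The cytosolic HSP90.1 rose (1.54), and adjusted over the list alone 3 rose and 7 fell. That list had a median of −0.65 (adjusted p = 0.0475, and adjusted p = 0.425 with an estimated correlation), and 4 of the 8 fits without 1 library did not call it, with an adjusted p of up to 0.0871.

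The largest changes past the test in wild type lay outside the photosynthesis lists as well as within them. Among the rises, AT1G30170 and AT5G53230, both genes of DUF295 proteins, were at least 199-fold and at least 116-fold higher. The ATPase-like gene AT4G05380 and the uncharacterized AT3G54520 were at least 153-fold and at least 120-fold higher. All 4 had 0 reads on MS, and the bound takes 3 reads over the group as its floor. The efflux carrier gene AT2G04050 rose by 7.46 ± 0.85 (adjusted p = 7.41e-05), and AT2G18193, another ATPase-like gene, rose by 6.92 ± 0.46 (adjusted p = 1.08e-06). Among the falls, the iron transporter gene IRT1 (AT4G19690), AFL1 (AT3G28270) and CYP82C4 (AT4G31940) had 0 reads on lincomycin and were at least 766-fold, at least 424-fold and at least 326-fold lower. Such bounds and intervals cover counting error only.

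Wall, tissue and reference lists completed the wild-type comparison. Of 29 secondary wall and xylem genes 7 fell and 1 rose, over all genes and adjusted over the list alone, and the list was not called (median −0.39, adjusted p = 0.0560). The xylan gene IRX15L fell (−2.27) and IRX14 rose (1.01), calls that 2 and 3 of the 8 fits without 1 library did not make (adjusted p up to 0.170 and 0.165). Of 9 primary wall cellulose genes 3 rose and 1 fell, over all genes and adjusted over the list alone (CESA5 0.68, CESA2 −0.59; median 0.13, adjusted p = 0.274). Of 9 root tissue markers 6 fell and 1 rose, over all genes and adjusted over the list alone, with the root hair expansin genes EXPA18 and EXPA7 at −4.72 ± 0.81 and −3.61 and the phosphate transporter PHT1;1 at −2.28. The root list had a median of −2.05 (adjusted p = 0.0301, and adjusted p = 0.458 with an estimated correlation), and without wild-type MS replicate 2 its adjusted p was 0.0875. Of 4 phloem markers PP2-A1 (0.41, 13.3% covered by another gene) and APL (0.67) rose, over all genes and adjusted over the list alone, and the list was not called (median 0.29, adjusted p = 0.124). Both calls were lost in some fits without 1 library (3 and 2 of 8, adjusted p up to 0.122 and 0.0677). The flavonoid and anthocyanin list (21 genes, 3 higher and 6 lower, over all genes and adjusted over the list alone) was not called (median −0.23, adjusted p = 0.614). Nor was the salicylate and pathogen list (8 genes, 2 higher and 3 lower, or 3 and 3 adjusted over the list alone, median −0.26, adjusted p = 0.948). Circadian clock genes (10 genes, 1 higher and 3 lower, median −0.02, adjusted p = 0.837), seed storage and maturation genes (11 genes, 2 lower, median −0.51, adjusted p = 0.235) and reference genes (7 genes, 1 higher and 2 lower, median −0.16, adjusted p = 0.469) were not called either. Their counts were the same adjusted over the list alone. ACT2 was the reference gene that changed most (−0.86, adjusted p = 2.92e-04).

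In all, lincomycin changed 5921 of 20251 tested genes in wild type at adjusted p = 0.05, 2431 higher and 3490 lower, and 3009 of them changed at least 2-fold (900 higher, 2109 lower). Without wild-type lincomycin replicate 1 or 3 the count was 3299 or 3323. The authors' deposited adjusted p called 5060 genes, of which 4973 were among the 5921.

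In irx3-2, lincomycin lowered the same photosynthesis lists. All 20 antenna genes, all 32 nuclear photosystem genes, all 18 Calvin-Benson genes and all 23 plastid-encoded photosynthesis genes fell, over all genes and adjusted over the list alone, with medians of −4.29, −3.67, −3.15 and −3.40. LHCB1.2 fell 66.1-fold (log2 −6.05 ± 0.11 SE, adjusted p = 8.57e-11), and LHCB1.4 (−8.73 ± 0.13), the carbonic anhydrase gene CA1 (AT3G01500, −7.68 ± 0.13), RBCS2B (−7.47 ± 0.18), RBCL (−6.35) and PSBA (−5.12) fell too. LHCB2.3 (AT3G27690), covered to 37.6% by another gene, changed by −8.49 ± 0.17. Camera gave adjusted p = 1.16e-28, 8.16e-41, 8.09e-23 and 9.94e-25, and adjusted p = 0.127 with an estimated correlation for each. CESA7 itself fell 2.07-fold (−1.05 ± 0.16, adjusted p = 4.70e-04).

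The other chloroplast lists in irx3-2 moved as follows. Of 27 tetrapyrrole genes 23 fell and none rose, over all genes and adjusted over the list alone (median −1.44, adjusted p = 7.58e-17, and adjusted p = 0.127 with an estimated correlation). All 23 plastid ribosomal protein genes fell, over all genes and adjusted over the list alone (median −1.15, adjusted p = 7.58e-17, and adjusted p = 0.177 with an estimated correlation). Of the 8 genes read by the nuclear-encoded polymerase 7 rose and ACCD fell (−0.32), over all genes and adjusted over the list alone. RPOC2 rose by 2.42, RPOB by 2.32 and RPOC1 by 2.16 (list median 1.01, adjusted p = 5.87e-04, and adjusted p = 0.177 with an estimated correlation). The plastid transcription machinery (5 higher and 4 lower of 13, over all genes and adjusted over the list alone, median 0.21, adjusted p = 0.687) was not called. The greening regulators (4 higher and 4 lower of 9, or 5 and 4 adjusted over the list alone, median 0.22, adjusted p = 0.725) were not called either, with GLK1 at −1.78 and GLK2 at −1.07.

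Flavonoid and anthocyanin genes rose on lincomycin in irx3-2. Of 21 members 15 rose and 1, the repressor gene MYBL2 (−3.59), fell, over all genes and adjusted over the list alone. Flavonoid 3'-hydroxylase (F3'H) rose by 2.45 and chalcone synthase (CHS) by 1.78 ± 0.09, and the list median was 1.32 (camera adjusted p = 1.30e-05, and adjusted p = 0.177 with an estimated correlation). Jasmonate genes fell (8 of 11, over all genes and adjusted over the list alone, AOC2 −7.90 and LOX2 −6.68, median −2.07, adjusted p = 9.60e-07, and adjusted p = 0.150 with an estimated correlation). Abscisic acid and dehydration genes fell (14 of 18, or 15 adjusted over the list alone, COR15A −5.74, median −1.38, adjusted p = 1.27e-06, and adjusted p = 0.131 with an estimated correlation). All 11 glucosinolate genes fell, over all genes and adjusted over the list alone, with CYP79F1 at −5.52, CYP83A1 at −2.82 and MAM1 at −2.12 (median −1.37, adjusted p = 1.44e-07, and adjusted p = 0.127 with an estimated correlation). Phenylpropanoid genes (6 lower and 1 higher of 17, or 7 and 1 adjusted over the list alone, PAL4 −1.92 and 4CL1 −1.68, median −0.31) gave adjusted p = 0.00782, and adjusted p = 0.373 with an estimated correlation. Salicylate genes (4 lower of 8, or 7 adjusted over the list alone, EDS5 −1.83, median −0.75) gave adjusted p = 0.00867, and adjusted p = 0.221 with an estimated correlation. Of these the calls of WRKY70 and PAD4 were each lost in 5 of 8 fits without 1 library, and that of PAD3 in 1. Secondary wall genes (8 lower and 1 higher of 29, or 6 and 1 adjusted over the list alone, median −0.56) gave adjusted p = 0.00782, and adjusted p = 0.204 with an estimated correlation. Among them the calls of IRX9, IRX14 and LAC17 were lost in 7, 2 and 1 of 8 fits without 1 library. The mitochondrial dysfunction genes UPOX, ANAC013 and AOX1A rose (6.24, 2.23 and 1.76, 3 of 5, over all genes and adjusted over the list alone, median 1.76, adjusted p = 0.00388, and adjusted p = 0.127 with an estimated correlation).

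Heat shock genes (6 higher and 2 lower of 13, or 6 and 4 adjusted over the list alone, median 0.11, adjusted p = 0.399) were not called in irx3-2, although HSP90.1 rose by 2.74 and HSP70-4 by 1.69. Of the largest single rises, AT3G54520 was at least 134-fold higher, AT2G18193 rose by 7.71 ± 0.46, and AT1G30170, with 2 reads on MS, was higher by a ratio of 415 (95% counting interval 115 to 3427). The iron-regulated transcription factor gene BHLH100 (AT2G41240) was among the largest falls (−7.35 ± 0.30, adjusted p = 2.06e-08). Root markers (1 higher and 2 lower of 9, over all genes and adjusted over the list alone, median −1.43, adjusted p = 0.247) were not called in the mutant. Nor were the primary wall, phloem, clock, seed and reference lists (adjusted p = 0.977, 0.103, 0.275, 0.697 and 0.977).

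Lincomycin changed 6835 genes in irx3-2, 3197 higher and 3638 lower, and 3490 of them at least 2-fold (1369 higher, 2121 lower). Without irx3-2 lincomycin replicate 2 the count was 3829, and without irx3-2 MS replicate 1 more genes were higher (3674) than lower (3561). The authors' deposited adjusted p called 5800 genes, of which 5735 were among the 6835. Genes higher in both genotypes numbered 1616 (384 if the calls were independent), genes lower in both 2520 (627), and 47 changed in opposite directions.

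On MS, irx3-2 seedlings differed from wild type in 44 genes, and those higher in the mutant included genes of storage oil use. ICL (AT3G21720) and MLS (AT5G03860), isocitrate lyase and malate synthase of the glyoxylate cycle, were 11.6-fold and 7.04-fold higher (log2 3.54 ± 0.28 SE, adjusted p = 6.05e-04, and 2.81 ± 0.34, adjusted p = 0.00938). ICL stood at 274 ± 139 normalized counts (SD, n = 2) in wild type and 3032 ± 753 in irx3-2. The defensin-like gene LCR67 (AT1G75830, 5.00 ± 0.53, adjusted p = 0.00556), the endoglucanase gene GH9B15 (AT4G23560, 2.55 ± 0.27) and the cysteine protease gene CP1 (AT4G36880, 2.06 ± 0.21) were higher too. These 5 calls held in all 8 fits without 1 library. The lipid droplet protein gene LDAP2 (AT2G47780) was higher by 3.04 ± 0.43 (adjusted p = 0.0216), a call that 5 of those 8 fits did not make (adjusted p up to 0.0963).

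Of 11 seed storage and maturation genes SESA1 and the oleosin gene OLEO2 were higher on MS, or 8 adjusted over the list alone, with a median of 2.38, or 2.35 with genes at 0 reads set at their bounds. SESA1 was at least 21.7-fold higher and OLEO2 was higher by 2.77 ± 0.39 (adjusted p = 0.0206), calls that 6 of 8 fits without 1 library did not make in either case (adjusted p up to 0.100 and 0.0950). Camera called the seed list (adjusted p = 1.69e-10, and adjusted p = 0.152 with an estimated correlation). LHCB2.2 was the only member of the antenna list past the test (0.70 ± 0.11, adjusted p = 0.0310, and up to 0.159 in the 7 of 8 fits without 1 library that did not call it). Of the 20 members 16 were higher adjusted over the list alone. The antenna list (median 0.39, adjusted p = 3.90e-12, and adjusted p = 0.407 with an estimated correlation) was called higher. The nuclear photosystem list (0 genes, or 9 higher adjusted over the list alone, median 0.26, adjusted p = 7.05e-12, and adjusted p = 0.449 with an estimated correlation) was called higher too. The jasmonate list (0 genes, or 3 higher adjusted over the list alone, median 0.70, LOX2 0.76 ± 0.14 at adjusted p = 0.0843) was called as well (adjusted p = 9.60e-05, and adjusted p = 0.407 with an estimated correlation). At an unadjusted p under 0.05 limma gave 17 photosystem and 3 jasmonate genes, all higher, and past adjusted p = 0.05 edgeR gave 0 and 1 and DESeq2 5 and 3.

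Transcripts lower in irx3-2 on MS included mitochondrial ribosomal RNA and 2 of 11 glucosinolate genes. RRN26 (ATMG00020), the large mitochondrial ribosomal RNA, was 2.49-fold lower (−1.32 ± 0.11, adjusted p = 0.00122), and RRN18 (ATMG01390) was lower too (−1.52 ± 0.22, adjusted p = 0.0229). The mitochondrial open reading frame ORF107A (ATMG00030) was also lower (−3.13 ± 0.37, adjusted p = 0.00938, and 0.0746 without wild-type MS replicate 3). The RRN18 call was lost in 5 of 8 fits without 1 library (adjusted p up to 0.0963). CYP79F1 (AT1G16410) and MAM1 (AT5G23010), both of aliphatic glucosinolate synthesis, were lower (−2.18 ± 0.36 and −1.58 ± 0.22, adjusted p = 0.0480 and 0.0197). These calls were not made in 6 and 3 of the 8 fits (adjusted p up to 0.221 and 0.125). The glucosinolate list (2 lower of 11, or 1 higher and 5 lower adjusted over the list alone, median −0.34) was called (adjusted p = 0.00769, and adjusted p = 0.407 with an estimated correlation). It was not called without wild-type MS replicate 2 or irx3-2 MS replicate 1 (adjusted p up to 0.100). The plastid transcription machinery (0 genes, or 1 lower adjusted over the list alone, median −0.33) was called lower (adjusted p = 3.66e-04, and adjusted p = 0.407 with an estimated correlation). So were the heat shock genes (0 genes, or 2 lower adjusted over the list alone, median −0.22, adjusted p = 0.00541, and adjusted p = 0.449 with an estimated correlation). The root markers (0 genes, median −0.67) were called at adjusted p = 0.0341, and adjusted p = 0.686 with an estimated correlation, but not without wild-type MS replicate 2 or irx3-2 MS replicate 1 (adjusted p up to 0.761). At an unadjusted p under 0.05 limma gave 5, 4 and 1 lower genes of the transcription, heat shock and root lists, and past adjusted p = 0.05 edgeR gave 0 of each and DESeq2 1, 1 and 0.

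CESA7 was the only secondary wall gene past the test on MS, and the secondary wall list was not called (1 higher of 29, or 1 higher and 1 lower adjusted over the list alone, median 0.02, adjusted p = 0.432). The plastid ribosomal protein list (median −0.02, adjusted p = 0.850) was not called, although it was without irx3-2 MS replicate 1 (adjusted p = 0.00353) and, in the other direction, without irx3-2 MS replicate 2 (0.00149). The flavonoid list (median 0.12, adjusted p = 0.177), the plastid-encoded photosynthesis list (0.12, adjusted p = 0.0980) and the tetrapyrrole list (0.00, adjusted p = 0.572) were not called. LHCB1.2 did not pass (0.44 ± 0.11, adjusted p = 0.169), although the authors' deposited DESeq2 test called it (0.44, adjusted p = 0.00735). In all 44 genes passed, 32 higher and 12 lower in irx3-2, and 2734 had an unadjusted p under 0.05. The count rested on single libraries: it was 901 without irx3-2 MS replicate 1, 29 without wild-type MS replicate 3, 15 and 16 without wild-type lincomycin replicate 1 and 3, and 18 without either irx3-2 lincomycin library. The balance of directions rested on the irx3-2 MS libraries, since 226 genes were higher and 675 lower without replicate 1, and 18 higher and 34 lower without replicate 2. The lincomycin libraries enter this comparison only through the spread per gene, which the fit shares over the 4 groups. The SD of the log2 difference between the 2 libraries of a group was 0.700 in wild type and 0.776 in irx3-2 on MS. On lincomycin it was 0.425 and 0.491. The count of 44 here and that of 1150 on lincomycin are therefore not on an equal footing. The authors' deposited adjusted p called 148 genes, which included all 44.

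**Figure D2:**
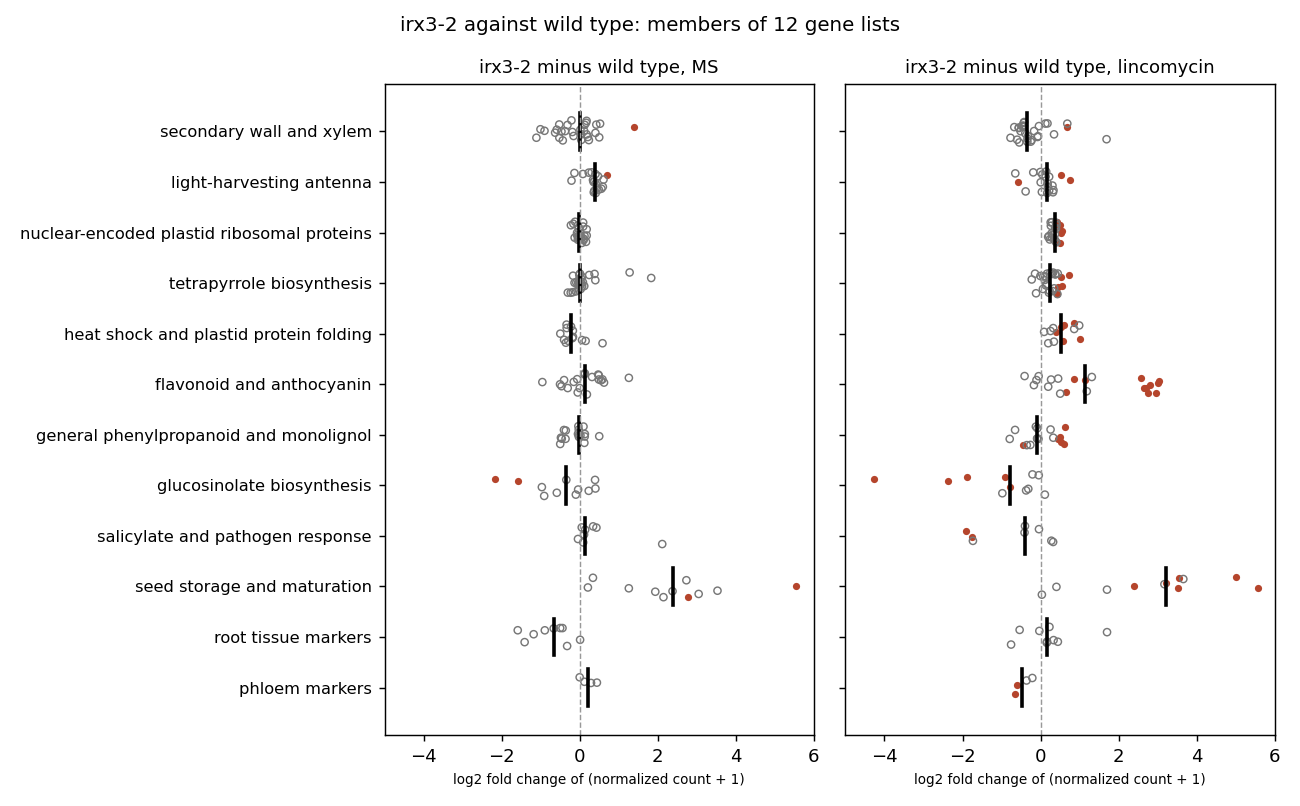
Log2 change in irx3-2 against wild type (horizontal axis) of each tested member of 12 gene lists, on MS (left) and on lincomycin (right). Filled red points passed adjusted p = 0.05, open grey points did not, and the black bar is the list median; the flavonoid median was 0.12 on MS and 1.15 on lincomycin.

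On lincomycin the genotypes differed in 1150 genes, and irx3-2 held more transcript for anthocyanin synthesis. Of 21 flavonoid and anthocyanin genes 11 were higher in irx3-2, or 14 adjusted over the list alone, and none was lower. The dioxygenase gene LDOX, the reductase gene DFR, F3'H and the glycosyltransferase gene UGT79B1 were higher by 3.01 ± 0.26, 2.97 ± 0.23, 2.80 ± 0.29 and 3.03 ± 0.29 (adjusted p = 2.16e-04, 1.16e-04, 6.96e-04 and 4.16e-04). The list median was 1.15 (camera adjusted p = 2.95e-13, and adjusted p = 0.117 with an estimated correlation).

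Some seed storage, plastid ribosome and folding genes were also higher in irx3-2 on lincomycin. Of 11 seed storage genes 6 were higher, or 9 adjusted over the list alone, with SESA2 at least 59.5-fold, SESA1 at least 35.5-fold, OLEO2 by 3.54 and CRA1 by 3.52. The list median was 3.21 (camera adjusted p = 2.02e-09, and adjusted p = 0.117 with an estimated correlation). The CRA1 and SESA1 calls were lost in 2 and 4 of the 8 fits without 1 library (adjusted p up to 0.0957 and 0.0843). Of 23 plastid ribosomal protein genes 6 were higher, or 21 adjusted over the list alone, with PRPL13 at 0.55 ± 0.10 (adjusted p = 0.0139). The list median was 0.37 (camera adjusted p = 1.10e-11, and adjusted p = 0.421 with an estimated correlation). Of 13 heat shock and plastid folding genes 6 were higher, or 8 adjusted over the list alone, among them HSP70-4 (1.00), HSP90.1 (0.86), CPN60A (0.59) and CPHSC70-1 (0.57). The median over the list was 0.53 (camera adjusted p = 8.63e-08, and adjusted p = 0.140 with an estimated correlation). Of 27 tetrapyrrole genes 5 were higher, or 10 adjusted over the list alone, with DVR at 0.74, GSA2 at 0.54 and CHLI1 at 0.51 (median 0.25, adjusted p = 7.47e-06, and adjusted p = 0.421 with an estimated correlation). The calls of these ribosomal, folding and tetrapyrrole genes were each lost without 1 of the lincomycin libraries, in 3 or 4 of the 8 fits, with adjusted p up to 0.294.

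Some glucosinolate, phloem and salicylate genes were lower in irx3-2 on lincomycin. CYP79F1, MAM1 and CYP83A1 were lower (−4.27 ± 0.36, −2.37 and −1.89), among 5 of 11 glucosinolate genes, or 6 adjusted over the list alone (median −0.78, adjusted p = 1.85e-07, and adjusted p = 0.117 with an estimated correlation). Of 4 phloem markers APL (−0.67) and PP2-A1 (−0.60) were lower, or 3 adjusted over the list alone (median −0.48, adjusted p = 6.94e-04, and adjusted p = 0.117 with an estimated correlation). Both calls were lost in 4 of the 8 fits without 1 library (adjusted p up to 0.258 and 0.153). The salicylate genes WRKY70 and CBP60G were lower (−1.91 and −1.75), 2 of 8 members over all genes and adjusted over the list alone (median −0.41, adjusted p = 0.0120, and adjusted p = 0.421 with an estimated correlation). Without irx3-2 lincomycin replicate 2 the list's adjusted p was 0.110. WRKY70 was not called without wild-type lincomycin replicate 1 (adjusted p = 0.0712), and CBP60G in 3 of the 8 fits (up to 0.143).

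Other large differences on lincomycin included AT2G07739, a Ycf1 protein gene on chromosome 2 within a copy of mitochondrial sequence, higher by 4.57 ± 0.22 (adjusted p = 4.38e-06). The Brix-domain genes BRX1-2 (AT1G52930, 3.72 ± 0.17, adjusted p = 4.38e-06) and IMP4 (AT1G63780, 3.76 ± 0.36, adjusted p = 4.10e-04), whose products act in ribosome assembly, were higher as well. The late embryogenesis gene ABR (AT3G02480) was higher by 4.40 ± 0.26 (adjusted p = 1.80e-05) and the mechanosensitive channel gene MSL9 (AT5G19520) by 3.53 ± 0.44 (adjusted p = 0.00187). The defensin-like AT1G13609 and the thionin gene AT1G66100 were lower (−4.62 ± 0.35 and −3.10 ± 0.25), as were the latex-protein-like gene MLP328 (AT2G01520, −3.78 ± 0.33) and the iron-regulated transcription factor gene BHLH101 (AT5G04150, −3.21 ± 0.32).

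Photosynthesis genes on lincomycin differed between the genotypes in few cases. In the antenna list LHCB1.1 (0.74 ± 0.10) and LHCA6 (0.53) were higher and LHCB1.4 (−0.57) lower, or 4 and 2 adjusted over the list alone, and the list was not called (median 0.16, adjusted p = 0.0948). These 3 calls were lost in 2, 6 and 4 of the 8 fits without 1 library (adjusted p up to 0.0829, 0.396 and 0.290). LHCB1.2 did not pass (0.33 ± 0.11, adjusted p = 0.106), although the authors' deposited DESeq2 test called it (0.33, adjusted p = 0.0392). None of the 32 nuclear photosystem genes passed, while camera called the list (median 0.10, adjusted p = 0.0448, and adjusted p = 0.758 with an estimated correlation). That call was not made in 5 of 8 fits without 1 library (up to 0.619). For the photosystem list limma gave 6 genes at an unadjusted p under 0.05, edgeR 0 and DESeq2 3 past adjusted p = 0.05. The plastid-encoded photosynthesis genes (0 past the test, or 5 unadjusted, 0 by edgeR and 4 by DESeq2, median −0.04, adjusted p = 0.592) and the Calvin-Benson genes (2 lower of 18, median 0.01, adjusted p = 0.862) were not called. Camera called the greening regulators (0 past the test, or 6 unadjusted, 1 by edgeR and 1 by DESeq2, median 0.33, adjusted p = 0.0120, and adjusted p = 0.421 with an estimated correlation). Without wild-type lincomycin replicate 3 the adjusted p of that list was 0.152. CESA7 alone passed among the secondary wall genes, and it was higher in irx3-2 (0.67). Camera called that list lower, opposite to CESA7 (median −0.34, adjusted p = 0.0491, and adjusted p = 0.421 with an estimated correlation). That call was lost in 6 of 8 fits (up to 0.166). The phenylpropanoid list (5 higher and 1 lower of 17, or 6 and 4 adjusted over the list alone, median −0.08, adjusted p = 0.710) and the reference list (1 higher of 7, median 0.08, adjusted p = 0.592) were not.

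In all, 1150 genes differed between the genotypes on lincomycin, 678 higher and 472 lower in irx3-2, and 326 of them at least 2-fold (181 higher, 145 lower). Without wild-type lincomycin replicate 1 or 3 the count was 177 or 116, without irx3-2 lincomycin replicate 2 or 3 it was 145 or 216, and without irx3-2 MS replicate 1 or 2 it was 1967 or 1917. Without irx3-2 lincomycin replicate 3 the balance turned, with 102 higher and 114 lower. The MS libraries enter this comparison only through the spread shared over the groups, and libraries of a group differed more on MS than on lincomycin. The authors' deposited adjusted p called 1434 genes, of which 1100 were among the 1150. Of the genes that differed on MS, 15 were also higher and 7 also lower on lincomycin (1.07 and 0.280 if the calls were independent), and 2 differed in opposite directions.

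**Figure D3:**
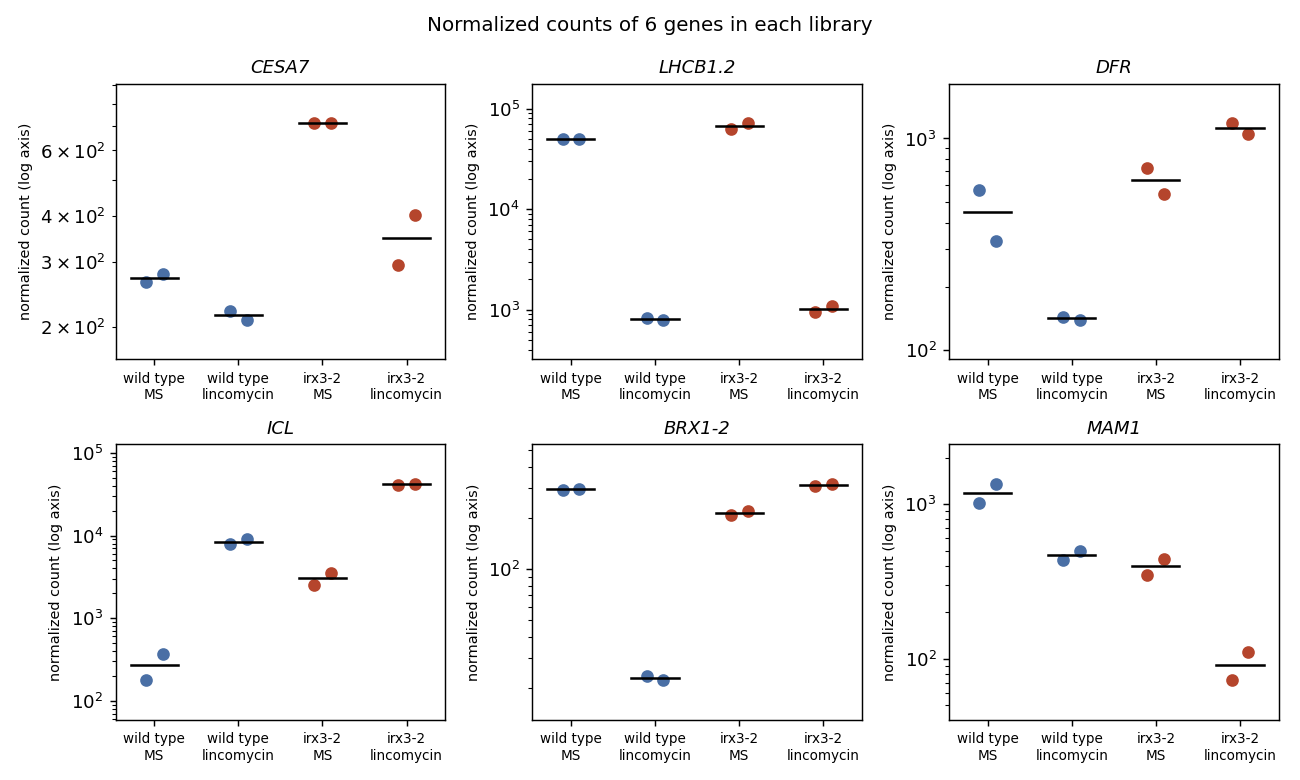
Normalized counts (log axis) of 6 genes in each of the 8 libraries, by genotype and medium; points are libraries and bars are group means. LHCB1.2 fell to 807 and 1017 on lincomycin in wild type and irx3-2, whereas BRX1-2 stood at 22.8 in wild type and 314 in irx3-2.

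The last comparison tested whether the response to lincomycin differed between the genotypes, gene by gene, and the flavonoid and heat shock lists had the highest medians of the difference among the 13 lists called. LDOX, DFR, F3'H and UGT79B1 responded more positively in irx3-2, by 2.88 ± 0.36, 2.42 ± 0.32, 2.62 ± 0.41 and 2.54 ± 0.41. DFR changed by −1.60 ± 0.23 on lincomycin in wild type and by 0.82 ± 0.23 in the mutant. Of 21 flavonoid genes 8 passed, all with a more positive response in irx3-2, or 10 adjusted over the list alone (median 1.26, camera adjusted p = 6.40e-11, and adjusted p = 0.206 with an estimated correlation). Of 13 heat shock and plastid folding genes HSP70-4 (1.29), CPN60B1 (0.82) and CPHSC70-1 (0.76) passed, or 7 adjusted over the list alone (median 0.74, adjusted p = 4.71e-10, and adjusted p = 0.206 with an estimated correlation). These gene calls were each lost in 3 to 6 of the 8 fits without 1 library, with adjusted p up to 0.260.

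Among photosynthesis genes LHCB1.2 did not pass the test of the interaction (−0.11 ± 0.15, adjusted p = 0.817). In the antenna list LHCB1.4 alone passed, with a more negative response in irx3-2 (−1.06, lost in 6 of 8 fits without 1 library, adjusted p up to 0.230), or 1 more positive and 4 more negative adjusted over the list alone. The antenna list (median −0.26, adjusted p = 3.24e-04, and adjusted p = 0.519 with an estimated correlation) was called more negative in irx3-2. So was the nuclear photosystem list (0 genes, median −0.18, adjusted p = 9.21e-04, and adjusted p = 0.519 with an estimated correlation). Without irx3-2 MS replicate 2 neither was called (antenna adjusted p = 0.0750), and the photosystem list was not called without irx3-2 lincomycin replicate 2 either (adjusted p up to 0.507). For the photosystem list limma gave 5 genes at an unadjusted p under 0.05, and edgeR and DESeq2 gave 0 past adjusted p = 0.05. With the preset correlation camera had called the antenna and photosystem lists higher in irx3-2 on MS. On lincomycin neither list had a negative median between the genotypes. The more negative response of these lists is thus not a lower level of the lists in irx3-2 on lincomycin. The Calvin-Benson list (median 0.02, adjusted p = 0.896) and the plastid-encoded photosynthesis list (−0.08, adjusted p = 0.416) were not called.

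Camera called lists of the plastid expression machinery as more positive in irx3-2. Plastid ribosomal protein genes (0 of 23, or 2 adjusted over the list alone, median 0.35, adjusted p = 5.92e-09) gave adjusted p = 0.411 with an estimated correlation. Plastid transcription genes (0 of 13, or 3 adjusted over the list alone, median 0.34, adjusted p = 8.82e-04) gave adjusted p = 0.350 with an estimated correlation. Genes read by the nuclear-encoded polymerase (0 of 8, median 0.50, adjusted p = 0.0184) gave adjusted p = 0.411 with an estimated correlation. The last of these was not called in 4 of 8 fits without 1 library (up to 0.148). At an unadjusted p under 0.05 limma gave 11, 3 and 2 genes of the 3 lists, and past adjusted p = 0.05 edgeR gave 0 of each and DESeq2 3, 2 and 0. Among 27 tetrapyrrole genes GSA2 passed (0.77, lost in 6 of 8 fits, up to 0.262), or 3 adjusted over the list alone (median 0.23, adjusted p = 9.21e-04, and adjusted p = 0.499 with an estimated correlation).

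Defence and hormone lists were called by camera as more negative in irx3-2. CBP60G (−2.18) and WRKY70 (−2.05) passed among 8 salicylate genes, or 3 adjusted over the list alone (median −0.43, adjusted p = 9.21e-04, and adjusted p = 0.350 with an estimated correlation). Their calls were lost in 7 and 6 of 8 fits without 1 library (up to 0.340 and 0.265). Jasmonate genes (0 of 11, or 2 adjusted over the list alone, median −0.48, adjusted p = 9.21e-04) gave adjusted p = 0.411 with an estimated correlation, and 0.0603 without wild-type MS replicate 3. Glucosinolate genes (0 of 11, or 2 adjusted over the list alone, median −0.44, adjusted p = 5.40e-04) and phloem markers (0 of 4, or all 4 adjusted over the list alone, median −0.63, adjusted p = 2.65e-05) each gave adjusted p = 0.206 with an estimated correlation. Abscisic acid genes (0 of 18, or 1 more positive and 3 more negative adjusted over the list alone, median −0.15, adjusted p = 0.0393) gave adjusted p = 0.499 with an estimated correlation. They were not called in 4 of 8 fits (up to 0.532). At an unadjusted p under 0.05 limma gave 3 jasmonate, 4 glucosinolate, 4 phloem and 5 abscisic acid genes, and past adjusted p = 0.05 edgeR gave 1, 0, 0 and 0 and DESeq2 1, 1, 2 and 2.

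Among single genes, BRX1-2 changed by −3.63 ± 0.17 on lincomycin in wild type and by 0.55 ± 0.17 in irx3-2, an interaction of 4.19 ± 0.24 (adjusted p = 4.64e-05). AT2G07739 (4.69 ± 0.32, adjusted p = 8.89e-05), ABR (3.97 ± 0.37, adjusted p = 0.00141) and RRN26 (3.59 ± 0.16, adjusted p = 6.24e-06) likewise responded more positively in irx3-2. These 4 calls held in all 8 fits without 1 library. RRN26 stood at 31404 ± 497 normalized counts in wild type on MS and 1816 ± 265 on lincomycin, against 12629 ± 744 and 8720 ± 315 in irx3-2. The interaction was negative for AT1G13609 (−4.58 ± 0.49, adjusted p = 0.00339), MLP328 (−3.77 ± 0.46, adjusted p = 0.00622) and AT1G66100 (−2.99 ± 0.36, adjusted p = 0.00555). It was negative too for the iron-regulated BHLH101 and BHLH100 (−3.28 ± 0.45 and −3.16 ± 0.42, adjusted p = 0.0106 and 0.0101). The first 3 of these were lost without either wild-type lincomycin library and the last pair without any 1 of the lincomycin libraries (adjusted p up to 0.0907 over the 5 genes).

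The interaction passed for 133 genes, 72 more positive and 61 more negative in irx3-2, and 2556 had an unadjusted p under 0.05. For 59 of the 133 the interaction was opposite in sign to the mean lincomycin effect, that is a smaller response in irx3-2, and for 74 it had the same sign. The count was 73 and 70 without wild-type MS replicate 2 and 3, 13 and 11 without wild-type lincomycin replicate 1 and 3, 302 and 357 without irx3-2 MS replicate 1 and 2, and 27 and 23 without irx3-2 lincomycin replicate 2 and 3. The balance of directions was not stable. It turned to 61 more positive and 72 more negative with TMM scaling, 93 and 98 with edgeR and TMM, and 14 and 15 with no filter. Without wild-type MS replicate 2 it was 31 and 42, and without irx3-2 lincomycin replicate 2 and 3 it was 10 and 17, and 11 and 12. Across the 9269 genes past the test for the mean lincomycin effect, the slope of the irx3-2 response on the wild-type response was 1.03. Its jackknife spread was 0.135, computed as if the 8 libraries were 1 group and not 4 groups of 2. The slope ran from 0.945 to 1.102 when 1 library was left out. Of the 5921 genes called in wild type, 5605 (94.7%) had the same direction in irx3-2, whether past the test there or not.

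**Figure D4:**
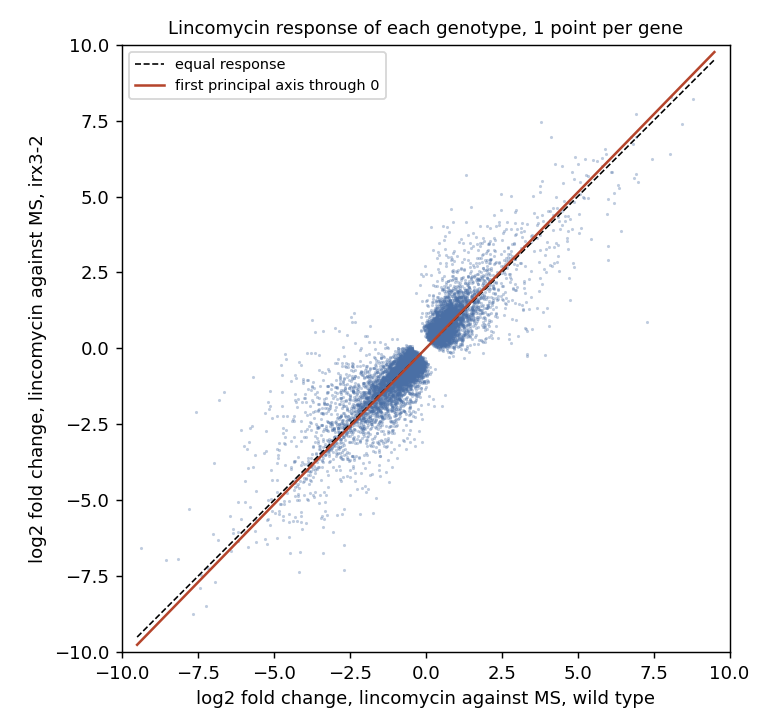
Log2 change on lincomycin in irx3-2 (vertical axis) against that in wild type (horizontal axis), 1 point per gene; the red line is the first principal axis through 0 and the dashed line an equal response. The slope over the 9269 genes past the test for the mean effect was 1.03.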

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

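The results in this part differ between the genotypes by the test of the interaction itself. The interaction test and its lists were planned before the data were examined, while the tests of explanations (ribosomal RNA removal, other mitochondrial transcripts, shared reads and other ribosome assembly genes) and the count over Brix-domain genes were chosen after the result was seen. The interaction passed for 133 genes in limma, 72 more positive and 61 more negative in irx3-2, and the balance turned with TMM scaling (61 and 72).

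Among the genes with the largest differences, AT2G07739 (4.69), MSL9 (4.43), BRX1-2 (4.19), ABR (3.97), IMP4 (3.66) and RRN26 (3.59) responded to lincomycin more positively in irx3-2 on the log2 scale. AT1G13609 (−4.58), MLP328 (−3.77), BHLH101 (−3.28), BHLH100 (−3.16), AT1G66100 (−2.99) and PELPK1 (−2.74) responded more negatively. Without 1 library MSL9 was lost in 4 of 8 fits (adjusted p up to 0.131), IMP4 in 3 (0.107), PELPK1 in 4 (0.155), BHLH101 and BHLH100 in 4 each (0.0907 and 0.0835), and AT1G13609, MLP328 and AT1G66100 in the fits without either wild-type lincomycin library (0.0560, 0.0749 and 0.0728).

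Among list members, LDOX (2.88), F3'H (2.62), UGT79B1 (2.54), DFR (2.42), HSP70-4 (1.29), CPN60B1 (0.82), GSA2 (0.77) and CPHSC70-1 (0.76) responded more positively in irx3-2, and CBP60G (−2.18), WRKY70 (−2.05) and LHCB1.4 (−1.06) more negatively. Each was lost in 3 to 7 of the 8 fits without 1 library, with adjusted p up to 0.340. List medians of the difference were 1.26 for flavonoid, 0.74 for heat shock and plastid folding, 0.50 for plastid genes read by the nuclear-encoded polymerase, 0.35 for plastid ribosomal proteins, 0.34 for plastid transcription and 0.23 for tetrapyrrole genes. They were −0.63 for phloem, −0.48 for jasmonate, −0.44 for glucosinolate, −0.43 for salicylate, −0.26 for antenna, −0.18 for nuclear photosystem and −0.15 for abscisic acid genes. With an estimated correlation all 13 lists lost their call (adjusted p = 0.206 to 0.519).

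The mitochondrial ribosomal RNA RRN26 was lower in irx3-2 on MS and higher in irx3-2 on lincomycin. Of 86 tested mitochondrion-encoded genes 3 passed for the interaction, all more positive in irx3-2. Besides RRN26 they were RRN18 (1.91, adjusted p = 0.0225) and ORF107A (3.31, adjusted p = 0.0216), both chosen after their values were seen. These 2 calls were lost in 4 and 6 of 8 fits without 1 library, in each fit without a lincomycin library and for ORF107A also without either wild-type MS library (adjusted p up to 0.211 and 0.165). All 3 fell on lincomycin in wild type (−4.12, −1.69 and −4.28) and were lower in irx3-2 on MS, while on lincomycin RRN18 (0.40, adjusted p = 0.381) and ORF107A (0.18, adjusted p = 0.870) did not pass between the genotypes. The calls of RRN18 and ORF107A on MS were lost in 5 and 1 of 8 fits (up to 0.0963 and 0.0746). A difference in all mitochondrial transcripts is argued against by the other 85 mitochondrion-encoded genes, whose median interaction was 0.329 (SD 0.820) against 3.59 for RRN26. Uneven removal of ribosomal RNA between libraries cannot be told apart from a change in the seedlings. RRN26 differed at most 1.23-fold between the 2 libraries of a group and at least 2.36-fold between genotypes, but RRN18 differed 1.83-fold between the wild-type MS libraries and 18S ribosomal RNA up to 2811-fold within a group. Reads shared with the mitochondrial copy on chromosome 2 were not tested and stay open. An effect of the genotype on RRN26 stays open as well.

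BRX1-2 and IMP4 encode Brix-domain proteins of ribosome assembly and were lower on lincomycin in wild type. Of the 6 genes whose annotation names this domain, BRX1-1 and MEE49 fell in wild type too and passed for the interaction (2.77, lost in 6 of 8 fits without 1 library, adjusted p up to 0.151, and 3.42), while PPAN (0.24) and AT3G23620 (0.01) did not pass there or for the interaction (adjusted p = 0.505 and 0.721). These genes were looked up after the values of the first were seen, so the family was not tested as a list. AT3G13180, which is outside it and was picked after its values were seen, went the same way (454 to 81.9 normalized counts in wild type, 397 to 812 in irx3-2). In wild type BRX1-2 went from 295 to 22.8 normalized counts, BRX1-1 from 94.97 to 14.1, IMP4 from 218 to 28.9 and MEE49 from 359 to 49.0, and in irx3-2 from 214 to 314, 129 to 132, 242 to 373 and 296 to 439. Reads moving between BRX1-1 and BRX1-2 are argued against, since the sum of both genes fell by 3.38 on the log2 scale (3.18 to 3.57 over the library pairings). A fall of ribosome assembly transcripts as a whole is argued against by 23 other genes (20 of ribosome assembly, PPAN, AT3G23620 and AT3G13180), with a median change of 0.223 (SD 0.727). A genotype-dependent response may be the source, but a variant in these seedlings' background was not tested and stays open.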

How the results depend on the processing

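The alternatives were planned, except pseudocounts of 0.5 and 5 and TMM scaling, which were chosen after the data were seen. In the plan edgeR with TMM was the main test, and it served here as an alternative on the recovered reads. Calls of lincomycin genes in each genotype stayed within 1.5 times the reported count under every tool, filter and scaling run. Requiring also a change of at least 1 on the log2 scale left 3009 in wild type, 3490 in irx3-2 and 326 for the genotypes on lincomycin. On MS the reported 44 genes became 144 with DESeq2, 148 by the authors' adjusted p, 25 with at least 10 CPM in 2 libraries, 4 with no filter, 18 with a replicate block and 7 with only the 4 libraries compared. On lincomycin the 1150 genes became 580 with no filter, 337 with the block and 3848 with only the 4 libraries compared. For the interaction the 133 genes became 29 with no filter and 24 with the block. DESeq2 called 426, of which 86 were among the 133, and it gave an adjusted p to 6158 genes only. The block and the 4-library fits leave 2 residual degrees of freedom in place of 4, which does not account for the rise to 3848. The 4-library fits also use the spread of the compared libraries alone. The SD of the log2 difference between the 2 libraries of a group was 0.700 and 0.776 on MS (wild type and irx3-2). On lincomycin it was 0.425 and 0.491. The cause of these moves was not tested further. The replicate numbers do not pair the samples (correlation of deviations between libraries with the same number −0.137 to 0.126), so the reported values use no block.

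Leaving out 1 library gave 3299 to 7110 genes for lincomycin in wild type, 3829 to 7262 in irx3-2, 15 to 901 for irx3-2 against wild type on MS (901 without irx3-2 MS replicate 1), 116 to 1967 on lincomycin and 11 to 357 for the interaction; the cause was not tested. In each of these fits the groups shared 1 spread per gene. A library left out therefore also changed the spread used in comparisons that do not hold it, such as an irx3-2 MS library for the genotypes on lincomycin. With an estimated correlation 0 lists were called in each of the 5 comparisons, against 14, 15, 8, 11 and 13 by camera with the preset value. Fry, which tests each list on its own, called more lists for lincomycin in wild type (21) and irx3-2 (17), and fewer between the genotypes on MS (1), on lincomycin (5) and for the interaction (3). The plastid ribosomal protein list on MS, not called as reported (adjusted p = 0.850), was called in the other direction without irx3-2 MS replicate 2 (0.00149), within a range of 0.00149 to 0.932 over the libraries left out; the cause was not tested.

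Of the named genes' values under the alternatives 8553 kept their direction and side of the threshold, 576 lost their call, 52 gained one and 0 reversed; of the lists' values 1279 kept both, 124 lost their call, 36 gained one and 1 reversed. The slope stayed between 0.930 and 1.145. Depth limits low genes: 1 read was 1.38 to 1.77 normalized counts on MS and 0.588 to 0.710 on lincomycin.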

Other observations

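The 4 gene groups and the tests of explanations in this part were chosen after the results were seen, and none was planned.

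DNA damage response genes rose on lincomycin in both genotypes. Of 14 tested genes 11 rose in wild type and 11 in irx3-2, with medians of 2.02 and 1.82 on the log2 scale. The cell cycle inhibitor gene SMR7 rose by 4.31 and 4.63, GMI1 by 3.65 and 4.34, the poly(ADP-ribose) polymerase gene PARP2 by 2.94 and 4.14 and BRCA1 by 2.29 and 2.82. With an estimated correlation the group did not pass in either once adjusted together with the 24 planned lists (adjusted p = 0.0798 and 0.0943). Adjusted over only the 4 groups chosen after their values were seen, the values were 0.0114 and 0.0135.

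Genes of the glyoxylate cycle and of fatty acid breakdown rose on lincomycin, and most were higher in irx3-2 on lincomycin. Of 18 genes 12 rose and 1 fell in wild type and 16 rose and 1 fell in irx3-2, with medians of 0.49 and 1.17 (adjusted p = 0.107 and 0.113 with an estimated correlation, over the planned lists and these groups together, as for the values that follow). In irx3-2 against wild type 2 were higher on MS and 12 on lincomycin (medians 0.22 and 0.73, adjusted p = 0.407 and 0.0979 with an estimated correlation), and ICL reached 41572 normalized counts in irx3-2 on lincomycin against 8467 in wild type. Iron deficiency genes fell on lincomycin, 14 of 19 in wild type and 18 of 19 in irx3-2, with medians of −2.10 and −3.77 (adjusted p = 0.215 and 0.142 with an estimated correlation). Of 21 ribosome assembly genes 7 rose and 1 fell in wild type and 13 rose in irx3-2 (adjusted p = 0.525 and 0.217 with an estimated correlation).

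Some seed storage and glyoxylate cycle transcripts were higher in irx3-2. Of 11 seed genes SESA1 and OLEO2 passed on MS, both lost in 6 of 8 fits without 1 library (adjusted p up to 0.100 and 0.0950), and 6 passed on lincomycin, of which CRA1 and SESA1 were lost in 2 and 4 fits (up to 0.0957 and 0.0843). CRB (0.34 on MS and 1.70 on lincomycin) and PAP85 (0.21 and 0.03) did not pass on either medium, and the seed list gave adjusted p = 0.152 and 0.117 with an estimated correlation. Ungerminated seeds in the irx3-2 libraries cannot be told apart from a change in the seedlings. For the glyoxylate part the gain of ICL on MS was 7.21 times that of the storage protein gene CRA1 (6.34 to 8.88 over the library pairings), but no seed library gives this ratio in seeds, and CRA1 did not pass on MS (adjusted p = 0.0614). For the storage part the log2 ratio of CRA1 to CRB differed by at least 0.717 between genotypes, but CRB held only 6.15 to 50.3 normalized counts. A delay of irx3-2 that includes greening cannot be told apart either. The antenna list had a median of 0.388 on MS with 18 of 20 genes above 0, but 1 gene passed, lost in 7 of 8 fits (adjusted p up to 0.159), and the list gave adjusted p = 0.407 with an estimated correlation. By camera the plastid transcription list was called lower on MS (median −0.33, adjusted p = 3.66e-04, and adjusted p = 0.407 with an estimated correlation). The nuclear photosystem list was called higher there, and not with an estimated correlation either. At an unadjusted limma p under 0.05, 0 of 13 transcription genes were higher and 5 lower. Of 32 photosystem genes 17 were higher and 0 lower. These lists went opposite ways, and whether either marks a delay was not tested. Slower use of seed reserves in irx3-2 stays open and was not tested.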
